A study of Mus musculus with 38 samples.

How the data were processed

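RNA was sequenced from hearts of mouse embryos at embryonic day 10.5 (E10.5), when the heart is a looped tube and its outflow tract is being remodelled. Per the labels, the embryos carried a CRISPR/Cas9 knockout or mutation of 1 of 6 ciliary genes (Agbl2, Pkhd1l1, Ppef2, Sptbn5, Tekt3 or Mlf1) on the C57BL/6J background, or were wild-type littermates of the same strain. Total RNA was extracted with TRIzol, and 2 µg per sample entered the NEBNext Ultra RNA kit, per the labels' protocols. There were 4 knockout and 4 wild-type libraries for Agbl2 and 3 of each for the other strains, 38 libraries in all. The labels do not say how many embryos made up a library or whether they were separate embryos or pools. Xist, expressed in females, made up 23.8 to 94.2% of Xist and Y-linked counts over the libraries. Every library thus held RNA of both sexes, which 1 embryo would not give. The labels also do not say which part of the embryo was dissected with the heart. The p-values therefore measure only the spread between these libraries, which may be technical. Titles of the wild-type libraries of Pkhd1l1, Ppef2, Sptbn5, Tekt3 and Mlf1 carry a number before the replicate number that the 3 libraries of a strain share, and titles of their knockout libraries and of Agbl2 do not. The labels do not explain it, so n counts libraries, which in Pkhd1l1, Sptbn5, Tekt3 and Mlf1 may be repeats of 1 sample. In Ppef2 the balance of Xist to Y-linked counts differed between the wild-type libraries by a chi-square per degree of freedom of 89.8, so there they were not all repeats of 1 sample.

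Reads were aligned by the authors with STAR 2.5.3a to GRCm38 (mm10), per the submitters' processing notes. The layout of the deposited tables is that of RSEM gene results; the RSEM version, the annotation release and the strand setting are not given in the sources used here. The expected count of each gene, per the file headers, is RSEM's estimated fragment count, fractional where fragments are shared between genes, and was deposited without normalisation. TPM, a length-scaled transcript share, per the file headers, is the authors' value scaled by effective transcript length and to the same sum in every library. FPKM, per the file headers, was deposited too and was looked at but not used here. The transcript length and effective length deposited by the authors differ by the mean fragment length, so the median of that difference over genes longer than 3000 bases gave each library's mean fragment length.

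Every table listed 48820 genes by versioned Ensembl ID. Symbols came from a gene name table matched on the ID without its version. In all, 48058 IDs (98.4%) matched, 83.2% of IDs in the same version. Expected counts were rounded to whole numbers before any test. In the library with most such values, 7.31% of values were not whole. Counts of genes with near-identical copies (haemoglobin genes, histones, ribosomal proteins and Ptma, which have many pseudogenes) and of overlapping or antisense genes are uncertain, because the counting divides shared fragments by estimate and no strand setting is stated. Coordinates of the targeted genes are those of GRCm38, 1-based.

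Library totals ran from 16599604 to 20796581 counts, so 1 count was worth about the same in every library. Fragments carry no molecular identifiers, so floors and counting intervals cover counting error only. A fold against a group in which every library was at 0 was computed against a floor of 3 counts over the group and is given as a lower bound.

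The following choices were made before the data were examined: the groups, the tests, the alternatives, the gene lists and the rule for named genes. Each strain was tested on its own libraries with edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3, robust fit), with TMM normalisation, edgeR's default filter on low counts and genotype as the only term. Adjusted p is the Benjamini-Hochberg value over the genes tested in that comparison, and genes under 0.05 are called changed, with no fold threshold. "Rose" and "fell" are used only for such genes. Standard errors of log2 fold changes were derived from the fold change and its test statistic. The effect common to the 6 strains was tested over all 38 libraries with strain as a covariate, and the difference of the effect between strains by the strain-by-genotype terms together. Means ± SD are TMM-normalised counts scaled by library total (CPM) unless stated. CPM for single libraries use the library total without TMM factors.

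There were 34 gene lists, of 1009 symbols of which 1007 matched a gene. They cover signalling pathways, cilia and tubulins, cardiac lineages and cell types, tissues next to the heart, metabolism, and signs of RNA quality. A gene can be in more than 1 list. The sex-linked list served only to check the embryos' sex. Each list was tested against the other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of the comparison. Its members were counted as passing over all genes tested and adjusted over the list alone. Camera was repeated with an estimated inter-gene correlation, which ended most calls, so that adjusted p is given with each list.

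The genes named are the targeted genes; the 8 largest rises and 8 largest falls per strain among genes with a mean of at least 5 CPM, no overlap between knockout and wild-type libraries and a symbol that is not of the Gm, Rik, accession or pseudogene kind; up to 3 passing members of each list per strain, by adjusted p; the 10 rising and 10 falling genes with the smallest p for the common effect; and genes called in the same direction in at least 4 strains.

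Alternatives were DESeq2 1.42.0, limma voom with quality weights, other size factors, no low-count filter, a filter of at least 5 CPM, limma on log2(TPM + 1) with a pseudocount of 1, all libraries in 1 fit, a fold threshold, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were the sum of each strain's wild-type libraries as 1 library, the common effect without wild-type library 3 of Ppef2, and the common effect with a score of endoderm genes as a covariate.

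The tests were tested on simulated data with the real libraries' means and totals, in which 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. At 1.5-fold, 97% of changed genes were recovered for Agbl2, 86.6% for Pkhd1l1, 58.2% for Ppef2, 88.1% for Sptbn5, 95.5% for Tekt3, 91% for Mlf1, 100% for the common effect and 76.1% for the difference between strains. At 2-fold, recovery was 88.1% for Ppef2, 98.5% for the difference between strains and 100% for the others, and at 4-fold it was 98.5% for Pkhd1l1 and for the difference between strains and 100% for the others. Unchanged genes called numbered 11 for Agbl2, 25 for Pkhd1l1, 19 for Ppef2, 23 for Sptbn5, 31 for Tekt3, 9 for Mlf1, 13 for the common effect and 6 for the difference. These false calls were over 5% of all calls in every comparison but Mlf1 and the difference between strains. The adjusted p may thus be somewhat too small there, but a single simulated set per comparison cannot measure by how much. Far fewer genes were changed in the simulation than were called in the real data.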

Results

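Gene expression was measured in 38 libraries of mouse hearts at E10.5, from 6 strains each carrying a knockout (KO) of 1 ciliary gene and from wild-type (WT) littermates of every strain. Each KO group was compared with the WT libraries of its own strain, with 4 libraries per group for Agbl2 and 3 per group for Pkhd1l1, Ppef2, Sptbn5, Tekt3 and Mlf1. The comparisons ask which genes change in the developing heart when a ciliary gene is disrupted, and whether the 6 strains share those changes. Library totals lay between 16599604 and 20796581 counts. Values after ± are standard deviations over the libraries of a group, and log2 fold changes are KO minus WT. The n given is the number of libraries, and the labels do not show that the WT libraries of a strain come from separate embryos.

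The targeted gene was lower in the KO libraries of Agbl2 and Pkhd1l1, but only the large fall of Pkhd1l1 checked the labels of its strain. Pkhd1l1 (ENSMUSG00000038725.12, chromosome 15, 44457494 to 44601369, plus strand), which encodes a large membrane protein related to fibrocystin, had 29, 29 and 28 counts in the KO libraries and 255, 280 and 308 in the WT libraries. Its level fell 10.1-fold, to 1.48 ± 0.0811 CPM from 14.9 ± 1.56 (log2 fold change −3.33, SE 0.162, adjusted p = 1.93e-08, n = 3 each). Agbl2 (ENSMUSG00000040812.14, chromosome 2, 90782727 to 90834437, plus strand), a carboxypeptidase that acts on tubulin, had 27, 25, 19 and 24 counts in KO and 37, 25, 44 and 35 in WT. It fell to 1.25 ± 0.191 CPM from 2.04 ± 0.5 (−0.70, SE 0.252, adjusted p = 0.0296, n = 4 each), and on log2(TPM + 1) the change was −0.26 with limma's adjusted p = 0.0739. The call rested on single libraries: edgeR's adjusted p was 0.087 without KO library 3, 0.0561 without KO library 4, and 0.0612, 0.107 and 0.0501 without WT library 1, 3 or 4.

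Sptbn5 (ENSMUSG00000074899.4, chromosome 2, 120041493 to 120085693, minus strand, annotated as a processed transcript), a beta spectrin, had 10, 13 and 8 counts in the libraries labelled KO and 21, 18 and 11 in WT (−0.75, SE 0.396, adjusted p = 0.171, n = 3 each). Mlf1 (ENSMUSG00000048416.15, chromosome 3, 67374097 to 67400003, plus strand), myeloid leukaemia factor 1, had 74, 63 and 63 counts in the libraries labelled KO and 50, 62 and 66 in WT. That difference did not pass the test (0.06, SE 0.209, adjusted p = 0.834), while on log2(TPM + 1) the gene was higher in KO by 0.38 (limma, adjusted p = 0.037). Ppef2 (ENSMUSG00000029410.11, chromosome 5, 92226679 to 92256278, minus strand), a protein phosphatase with calcium-binding EF hands, had 2, 2 and 0 counts in KO and 0, 0 and 2 in WT. Tekt3 (ENSMUSG00000042189.5, chromosome 11, 63061654 to 63094964, plus strand), a tektin of axonemal microtubules, had 0 counts in all 6 libraries of its strain. Expression of Ppef2 and Tekt3 was not detectable at this depth in either group, so their counts cannot check the labels, and gene-level counts do not show where in a gene the edit lies.

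**Figure D1:**
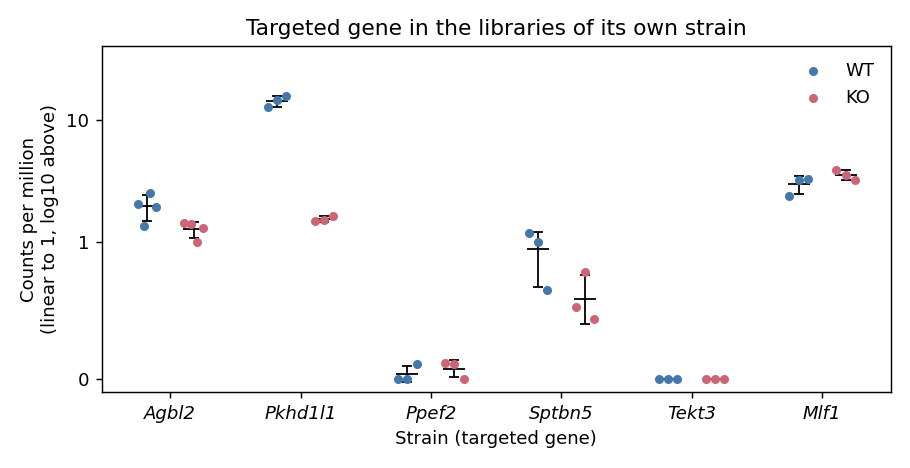
CPM of the targeted gene in each library of its own strain, on an axis that is linear to 1 and logarithmic above. Points are libraries and bars are means ± SD. Pkhd1l1 fell from 255 to 308 counts in WT to 28 or 29 in KO, and Tekt3 is at 0 throughout.

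Strain and genotype both separated the libraries. The first principal component held 62.3% of the variance and set Agbl2, Sptbn5 and Tekt3 (negative scores) apart from Pkhd1l1, Ppef2 and Mlf1 (positive scores). Mitochondrially encoded transcripts made up 2.46 to 4.58% of counts in Agbl2, Sptbn5 and Tekt3 and 0.453 to 1.42% in Pkhd1l1, Ppef2 and Mlf1, while mean fragment length did not follow these sets throughout. That length was 308.1 to 315.4 bases in Agbl2, 269.4 to 281.4 in Sptbn5 and Tekt3, 344 to 353 in Pkhd1l1, and 339.4 to 347.9 in Mlf1 except KO library 1 at 319.4. The second component, with 18.5%, placed KO libraries below the WT libraries of their strain. WT library 3 of Ppef2 scored −16.78 on this component, against 17.94 and 15.94 for WT libraries 1 and 2, and its mean fragment length was 354.9 bases against 266.4 and 264.5. The Ppef2 KO libraries were at 345.7 to 349.1 bases, so that without WT library 3 genotype and fragment length coincide in this strain. Its mean log2 CPM over foregut and lung endoderm genes was 3.36, while the highest of the other WT libraries of Ppef2 was 1.64 and the lowest Ppef2 KO library 3.43. The WT groups of the 6 strains differed from one another in 14377 of 15815 genes tested. WT triplicates of Pkhd1l1, Sptbn5, Tekt3 and Mlf1 varied little, with a chi-square per degree of freedom between pairs of libraries of 1.97 to 4.34, against 4.54 to 20.8 in their KO triplicates.

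**Figure D2:**
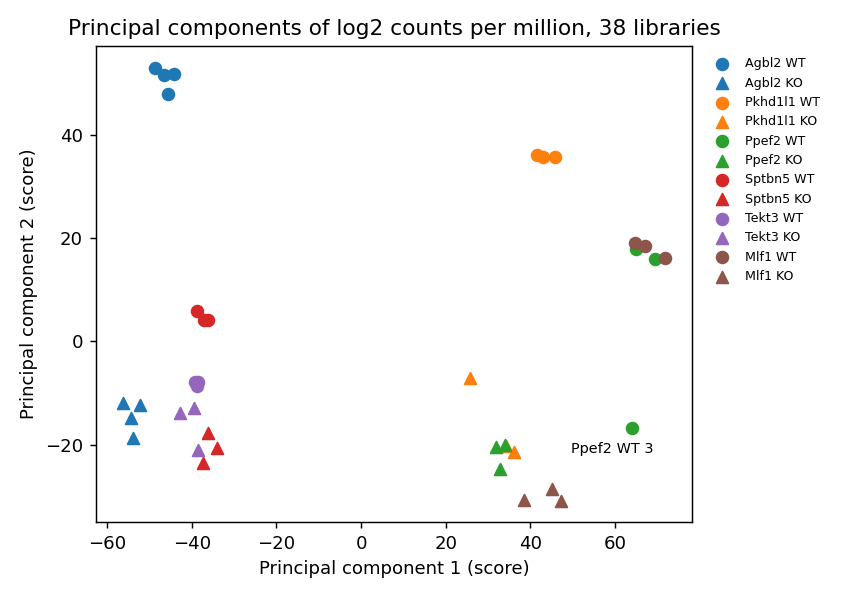
Scores of the 38 libraries on principal components 1 and 2 of log2 CPM. Circles are WT and triangles KO libraries, coloured by strain. KO libraries lie below the WT libraries of their strain on component 2, and WT library 3 of Ppef2, at −16.78, lies with the KO libraries.

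Shares of haemoglobin, mitochondrial, ribosomal protein and sex-linked counts were compared in each strain by two-sided exact permutation tests. None passed over the 24 comparisons, the smallest adjusted p being 0.218, and with 3 libraries against 3 the smallest possible exact p is 0.1. The ribosomal protein share in Agbl2 was 4.51 ± 0.221% in KO and 4.01 ± 0.148% in WT (exact p = 0.0286, the smallest that 4 against 4 can give, n = 4 each). The mitochondrial share in Mlf1 was 0.524 ± 0.107% in KO and 1.07 ± 0.0636% in WT (exact p = 0.1, n = 3 each). The share of Xist and 4 Y-linked genes was 0.01 ± 0.00106% in KO and 0.00249 ± 0.000294% in WT of Mlf1, and 0.0111 ± 0.00426% and 0.0028 ± 0.000968% in Ppef2 (exact p = 0.1 for both, n = 3 each). Xist is expressed from the inactive X chromosome of females. In Mlf1 it was at 78.1 to 111 CPM in KO and 14.5 to 18.3 in WT libraries. The Y-linked Ddx3y was at 0.83 to 2.18 and 1.65 to 2.59, and Kdm5d at 3.32 to 10.6 and 5.25 to 5.92. Each of the 4 Y-linked genes overlapped between KO and WT libraries of Mlf1. In Ppef2, Xist was at 37.6 to 145 CPM in KO and 13.4 to 37.2 in WT libraries.

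Agbl2 KO hearts held more transcripts of foregut endoderm, hedgehog signalling and outflow precursors than their WT hearts, and less mRNA of the contractile genes Ryr2 and Tnni1. Shh, the hedgehog ligand made by foregut endoderm, was at 26.4 ± 2.74 CPM in KO and had 0 counts in the 4 WT libraries, which is at least 633-fold higher. Nkx2-1, a transcription factor of lung and thyroid endoderm, was likewise at least 370-fold higher (15.4 ± 3.75 CPM against 0 counts). The hedgehog target genes Foxf1 and Gli1 rose 96.7-fold (59 ± 4.35 against 0.602 ± 0.174 CPM) and 35.9-fold (53.8 ± 5.11 against 1.5 ± 0.302). The calcium release channel Ryr2 fell 1.72-fold (229 ± 21 against 394 ± 16.5 CPM, adjusted p = 3.34e-09) and the troponin gene Tnni1 1.58-fold (791 ± 50.2 against 1250 ± 23.4).

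In all, 3267 genes rose and 3379 fell of 15072 tested (44.1%), and 732 of those that rose and 91 of those that fell changed by at least 1 log2 unit. All 20 tested genes of the foregut and lung endoderm list rose (20 adjusted over the list alone; adjusted p = 0.00335 with an estimated correlation), among them the epithelial genes Cdh1 (27.5 ± 3.03 against 0.144 ± 0.215 CPM) and Cldn6 (33.7 ± 3.82 against 0.188 ± 0.128). Foxa1 was at 14.1 ± 2.41 CPM in KO with 1 count over the WT libraries, and Tfap2b, a neural crest transcription factor, at 12 ± 1.71 CPM with 2. The mean log2 CPM of the endoderm list was −0.97 in these WT hearts, the lowest of the 6 WT groups, and 3.16 in KO. Of 15 lung and splanchnic mesenchyme genes, 13 rose and 0 fell (14 rose adjusted over the list alone; adjusted p = 0.00552 with an estimated correlation), and the lung mesenchyme transcript Fendrr rose 175-fold. Of 23 hedgehog pathway genes, 17 rose and 3 fell (17 and 3 adjusted over the list alone; adjusted p = 0.00335 with an estimated correlation).

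Among 22 second heart field genes, which mark the precursors of the outflow tract and right ventricle, 16 rose and 2 fell (16 and 3 adjusted over the list alone; adjusted p = 0.00552 with an estimated correlation). Six2 rose 119-fold, Isl1 3.54-fold (44.9 ± 3.6 against 12.7 ± 1.7 CPM) and Tbx1 23.4-fold. Of 25 neural crest genes, 21 rose and 2 fell (21 and 2 adjusted over the list alone; adjusted p = 0.0279 with an estimated correlation), and Sox10 rose 12-fold. FGF and retinoic acid genes rose in 22 of 31 cases and fell in 3 (22 and 3 adjusted over the list alone; adjusted p = 0.0241 with an estimated correlation). In that list the retinol receptor Stra6 rose 15.3-fold, and outside it the Wnt antagonist Sfrp2 rose 11.1-fold and the urea cycle enzyme gene Arg1 290-fold. Primary cilium genes rose in 31 of 70 cases and fell in 3 (34 and 3 adjusted over the list alone; adjusted p = 0.0787 with an estimated correlation), with Evc at 1.87-fold and Tctn1 at 1.5-fold.

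Of 48 sarcomere and calcium handling genes, 46 fell and 0 rose (46 adjusted over the list alone; adjusted p = 0.0808 with an estimated correlation). The sodium-calcium exchanger Slc8a1 fell 2.18-fold, myoglobin (Mb) 2.07-fold, Nrap 2.06-fold and the cardiac kinase gene Tnni3k 2.23-fold. Oxidative phosphorylation genes fell in 39 of 44 cases and rose in 0 (41 fell adjusted over the list alone; adjusted p = 0.235 with an estimated correlation), including Atp5a1 (1.44-fold). Among 37 endothelial and endocardial genes 21 fell and 7 rose (23 and 7 adjusted over the list alone; adjusted p = 0.491 with an estimated correlation). The endocardial regulator Nfatc1 fell 1.69-fold and the tight junction gene Cldn5 rose 4.88-fold. Rapgef5 (2.43-fold), Lgals9 (2.26-fold), Palm2 (2.2-fold) and Scube2 (2.18-fold) were the other large falls.

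Genes called in Agbl2 numbered 3598 when the WT libraries were summed to 1, an alternative chosen after the data were seen, and primary cilium genes that rose then numbered 16. On TPM 13 endothelial and endocardial genes were lower. Genes higher in KO made up 49.2% of calls, and 77% on TPM, where the median of all genes was higher by 0.134 log2 units.

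In Pkhd1l1 KO hearts endodermal genes were among the largest rises and Nppa and Gata4 fell, but none of the 20 list calls held with an estimated correlation (smallest adjusted p = 0.0642). Arg1 rose 150-fold (11.6 ± 3.01 against 0.0714 ± 0.0829 CPM), Shh 128-fold (19 ± 4.38 against 0.141 ± 0.123) and the epithelial cadherin Cdh1 48.4-fold (34.5 ± 4.68 against 0.708 ± 0.0919, adjusted p = 1.43e-10, n = 3 each). The natriuretic peptide gene Nppa fell 1.77-fold (1250 ± 91.4 against 2220 ± 85.6 CPM) and the cardiac transcription factor Gata4 1.56-fold (348 ± 9.82 against 544 ± 17.4). Besides the targeted gene, the matrix gene Postn had the largest fall among the named genes, 3.53-fold (13.2 ± 4.01 against 46.3 ± 0.985 CPM).

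Here 2742 genes rose and 3023 fell of 14449 tested (39.9%), 577 and 104 of them by at least 1 log2 unit. All 22 tested endoderm genes rose (22 adjusted over the list alone; adjusted p = 0.0795 with an estimated correlation), among them Cldn6 (63-fold) and Foxa1 (39.5-fold), and the list's mean log2 CPM was −0.05 in WT and 3.33 in KO. The signalling and transcription factor genes Wnt7b and Nkx6-1 rose 71.6-fold and 99.2-fold with wide spread (24.4 ± 12 and 18.1 ± 11.6 CPM in KO). Lung and splanchnic mesenchyme genes rose in 12 of 15 cases and fell in 1 (14 and 1 adjusted over the list alone; adjusted p = 0.215 with an estimated correlation), with Hoxb5 at 40.4-fold. Of 24 hedgehog genes 17 rose and 2 fell (17 and 2 adjusted over the list alone; adjusted p = 0.216 with an estimated correlation). The hedgehog receptor Ptch1 rose 3-fold (91.5 ± 10.8 against 30.5 ± 1.47 CPM) and Gli3 2.02-fold.

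Second heart field genes rose in 15 of 22 cases and fell in 2 (16 and 2 adjusted over the list alone; adjusted p = 0.0642 with an estimated correlation), with Isl1 at 3.16-fold and Hoxb1 at 1.76 ± 0.161 CPM against 2 counts over the WT libraries. Neural crest genes rose in 15 of 25 cases and fell in 4 (16 and 4 adjusted over the list alone; adjusted p = 0.219 with an estimated correlation), with Dlx2 at 4.53-fold. Of 31 FGF and retinoic acid genes 22 rose and 0 fell (23 rose adjusted over the list alone; adjusted p = 0.0809 with an estimated correlation), with the retinoic acid binding protein gene Crabp1 at 4.44-fold. The glucose transporter Slc2a3 rose 2.36-fold and the cilium gene Rab23 1.75-fold.

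Sarcomere and calcium handling genes fell in 42 of 47 cases and rose in 0 (43 fell adjusted over the list alone; adjusted p = 0.216 with an estimated correlation), with Tnni1 falling 1.62-fold. Oxidative phosphorylation genes fell in 40 of 44 cases and rose in 0 (41 fell adjusted over the list alone; adjusted p = 0.216 with an estimated correlation), with Cox4i1 falling 1.57-fold and the mitochondrially encoded mt-Co1 1.58-fold. Endothelial and endocardial genes fell in 24 of 37 cases and rose in 6 (24 and 6 adjusted over the list alone; adjusted p = 0.0642 with an estimated correlation), with the TGF-beta co-receptor Eng falling 1.72-fold and the endothelial nitric oxide synthase Nos3 1.78-fold. Cardiac transcription factor genes rose in 8 of 32 cases and fell in 10 (8 and 11 adjusted over the list alone; adjusted p = 0.681 with an estimated correlation), and on TPM 8 were higher and 5 lower, with a median of 0.119 against −0.079. Gja5 fell 1.63-fold, Nkx2-5 1.49-fold, Tgfb1 1.62-fold, Lgals9 2.92-fold, Papss2 2.84-fold, Clca3a1 2.79-fold, Ggt5 2.69-fold, and Col9a3 and P4ha3 both 2.42-fold. Ribosomal protein genes fell in 32 of 78 cases and rose in 6 (33 and 6 adjusted over the list alone; adjusted p = 0.842 with an estimated correlation), and on TPM 40 were higher and 1 lower.

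With the WT libraries of Pkhd1l1 summed to 1, 1715 genes were called. Then 20 endoderm, 7 lung and splanchnic mesenchyme, 8 hedgehog, 9 second heart field and 8 FGF and retinoic acid genes rose, and 15 endothelial and endocardial and 3 ribosomal protein genes fell. The share of calls that were higher in KO was 47.6%, and 83.3% on TPM, where the median of all genes was higher by 0.196.

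In Ppef2, single genes of muscle, endothelium and platelets fell in the libraries labelled KO, but none of the 12 list calls held with an estimated correlation (smallest adjusted p = 0.532). Desmin (Des), an intermediate filament of muscle, fell 1.75-fold (878 ± 21 against 1530 ± 94.4 CPM, adjusted p = 0.00129, n = 3 each), and the cardiac transcription factor Nkx2-5 1.79-fold (399 ± 24.9 against 716 ± 99.5). The endothelial receptor Tie1 fell 1.79-fold (198 ± 3.7 against 353 ± 22.4 CPM), and the platelet integrin Itga2b 2.21-fold (20.7 ± 0.72 against 45.7 ± 1.25). The long noncoding RNA Malat1 rose 3.95-fold (39 ± 3.47 against 9.88 ± 0.346 CPM), and Rbpj, the nuclear effector of Notch, 1.95-fold (48.2 ± 1.95 against 24.7 ± 3.1).

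Of 14424 genes tested, 3196 rose and 3234 fell (44.6%), 704 and 288 of them by at least 1 log2 unit. Without WT library 3, when KO and WT also differ in fragment length throughout, 4653 rose and 4441 fell. Counts in several lists moved with that library. Of 22 endoderm genes 2 rose and 0 fell (0 adjusted over the list alone; adjusted p = 0.927 with an estimated correlation), and without it 21 of 23 rose. Hedgehog pathway genes rose in 3 of 24 cases and fell in 3 (3 and 3 adjusted over the list alone; adjusted p = 0.927 with an estimated correlation), and without WT library 3 in 16 and 3. The receptor gene Gpr161 rose 1.65-fold and the ligand gene Dhh fell 1.96-fold. Second heart field genes rose in 8 of 22 cases and fell in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.916 with an estimated correlation), and without that library 15 rose and 2 fell. In this list the transcription factor Mef2c rose 1.5-fold and the ligand Wnt11 fell 1.56-fold. Neural crest genes rose in 6 of 25 cases and fell in 1 (6 and 0 adjusted over the list alone; adjusted p = 0.927 with an estimated correlation), with 18 and 3 without it, and Tfap2b rose 5.24-fold. Primary cilium genes rose in 24 of 69 cases and fell in 8 (24 and 8 adjusted over the list alone; adjusted p = 0.856 with an estimated correlation), with Arl13b at 2.82-fold.

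Sarcomere and calcium handling genes fell in 34 of 46 cases and rose in 2 (38 and 2 adjusted over the list alone; adjusted p = 0.856 with an estimated correlation), and Actn2 fell 1.66-fold. All 34 of the 44 oxidative phosphorylation genes that passed fell (40 adjusted over the list alone; adjusted p = 0.916 with an estimated correlation), and without WT library 3 all 44 fell. On TPM 18 were lower and 0 higher, with a median of −0.261 against −0.759. Uqcrc1 fell 1.83-fold, Cyc1 1.9-fold, Uqcr11 3.1-fold, Cox7a1 3.95-fold, Pet100 3.36-fold and mt-Nd4l 4.78-fold. Endothelial and endocardial genes fell in 20 of 37 cases and rose in 1 (20 and 1 adjusted over the list alone; adjusted p = 0.546 with an estimated correlation), and on TPM 10 were lower and 3 higher, with a median of −0.039 against −0.322. Nos3 fell 1.88-fold. Ribosomal protein genes fell in 34 of 78 cases and rose in 0 (25 fell adjusted over the list alone; adjusted p = 0.927 with an estimated correlation), and on TPM 21 were higher and 5 lower. Rps2 fell 1.62-fold and Rpl13a 1.78-fold, and without WT library 3, 75 ribosomal protein genes fell. Macrophage and platelet genes fell in 8 of 17 cases and rose in 0 (8 fell adjusted over the list alone; adjusted p = 0.532 with an estimated correlation), with Gp9 falling 3.12-fold and Gp1bb 2.85-fold.

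Other named rises in Ppef2 were Vezf1 (8.8-fold, with 11.3 ± 8.07 CPM in KO), Fendrr (6.78-fold), the mitochondrial rRNA mt-Rnr2 (4.04-fold), the splicing regulator Esrp1 (3.87-fold), Zfp397 (3.65-fold), Prrx1 (3.51-fold), Wasf3 (3.48-fold) and Ccnd2 (1.62-fold). Other falls were Gja5 (1.69-fold), Tgfb1 (1.84-fold), Rtl8c (3.3-fold), S100a13 (3-fold) and the myeloperoxidase gene Mpo (2.84-fold). Without a low-count filter 11 of 38 named genes were no longer called, namely Vezf1, Fendrr, mt-Rnr2, Esrp1, Prrx1, Wasf3, mt-Nd4l, Cox7a1, Pet100, Uqcr11 and S100a13. Leaving out WT library 2, KO library 2 or KO library 3 gave 3933, 4060 and 4215 genes. In Ppef2 the WT libraries were not all repeats of 1 sample. Summing them to 1 hides the spread of WT library 3, so list counts from that sum are not used. On TPM 10 endoderm, 11 hedgehog, 13 second heart field and 10 neural crest genes were higher, and 5 macrophage and platelet and 1 primary cilium gene lower. Of calls, 49.7% were higher in KO, and 88% on TPM, where the median of all genes was higher by 0.314.

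The libraries labelled Sptbn5 KO had less mRNA for contraction and for matrix than WT (adjusted p = 0.045 for both lists with an estimated correlation) and more of lung and splanchnic mesenchyme genes (adjusted p = 0.0432). Arg1 rose 6.32-fold (20.9 ± 8.57 against 3.3 ± 0.475 CPM, n = 3 each) and Shh 5.78-fold (33.9 ± 17.5 against 5.84 ± 0.613), both with a wide spread in KO. Crabp2, which carries retinoic acid, rose 3.35-fold (49 ± 4.02 against 14.6 ± 1.45 CPM, adjusted p = 5.72e-08), and Isl1 2.15-fold (35.9 ± 2.72 against 16.7 ± 0.303). The giant sarcomere protein gene Ttn fell 1.7-fold (1260 ± 94.6 against 2140 ± 1.02 CPM) and the basement membrane gene Lama4 1.6-fold (173 ± 4.39 against 277 ± 7.3).

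There were 2220 genes that rose and 2424 that fell of 15187 tested (30.6%), 275 and 109 of them by at least 1 log2 unit. Endoderm genes rose in 21 of 22 cases and fell in 0 (21 rose adjusted over the list alone; adjusted p = 0.0991 with an estimated correlation), including Cldn6 (4.65-fold), Foxa1 (4.57-fold) and Sox2 (4.51-fold), from a mean log2 CPM of 1.73 in WT to 3.40 in KO. Lung and splanchnic mesenchyme genes rose in 12 of 16 cases and fell in 0 (14 rose adjusted over the list alone; adjusted p = 0.0432 with an estimated correlation). Of 23 hedgehog genes 15 rose and 3 fell (16 and 3 adjusted over the list alone; adjusted p = 0.0584 with an estimated correlation), with Scube3 at 1.84-fold and Foxf2 at 2.41-fold. Second heart field genes rose in 13 of 22 cases and fell in 2 (14 and 3 adjusted over the list alone; adjusted p = 0.0881 with an estimated correlation), with Tbx1 at 2.36-fold. Neural crest genes rose in 16 of 26 cases and fell in 2 (17 and 2 adjusted over the list alone; adjusted p = 0.045 with an estimated correlation), and in that list Dlx2 rose 2.71-fold and the endothelin receptor Ednrb fell 1.66-fold. FGF and retinoic acid genes rose in 16 of 31 cases and fell in 2 (17 and 2 adjusted over the list alone; adjusted p = 0.045 with an estimated correlation).

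Sarcomere and calcium handling genes fell in 41 of 48 cases and rose in 0 (42 fell adjusted over the list alone; adjusted p = 0.045 with an estimated correlation), with Slc8a1 falling 1.73-fold, Ryr2 1.59-fold and the calsequestrin gene Casq2 2.25-fold. Extracellular matrix genes fell in 21 of 36 cases and rose in 3 (25 and 3 adjusted over the list alone; adjusted p = 0.045 with an estimated correlation), with Fbn1 falling 1.48-fold. Endothelial and endocardial genes fell in 21 of 37 cases and rose in 4 (23 and 5 adjusted over the list alone; adjusted p = 0.0494 with an estimated correlation), with the receptors Tek and Npr3 both falling 1.54-fold. Ribosomal protein genes rose in 64 of 78 cases and fell in 0 (71 rose adjusted over the list alone; adjusted p = 0.516 with an estimated correlation), Rpl12 by 1.18-fold, and cell cycle genes rose in 20 of 42 cases and fell in 1 (24 and 2 adjusted over the list alone; adjusted p = 0.204 with an estimated correlation), with Mcm5 at 1.24-fold. Oxidative phosphorylation genes fell in 35 of 44 cases and rose in 0 (40 fell adjusted over the list alone; adjusted p = 0.416 with an estimated correlation), with Uqcrc2 falling 1.27-fold. Other named genes that rose were Lin28a (5.06-fold), Wfikkn1 (4.97-fold), Eps8l2 (4.6-fold) and Ift74 (1.48-fold). Those that fell were Snap91 and Pdpr (both 2.4-fold), Aqp1 (2.37-fold), Papss2 (2.34-fold), Postn (2.26-fold), and Adamts5 and Slco2a1 (both 2.2-fold). The ligand gene Bmp10 (1.66-fold) and Tbx20 (1.48-fold) also fell.

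In Sptbn5, 878 genes were called with the WT libraries summed to 1, and 2829 on log2(TPM + 1), where 23 oxidative phosphorylation genes were lower. With the summed libraries 10 endoderm, 8 hedgehog, 8 second heart field, 8 neural crest, 7 FGF and retinoic acid, 0 cell cycle and 0 ribosomal protein genes rose, and 11 matrix and 2 oxidative phosphorylation genes fell. Of 37 named genes 13 were then no longer called, namely Arg1, Shh, Lin28a, Wfikkn1, Cldn6, Foxa1, Mcm5, Rpl12 and Ift74 among those that rose and Snap91, Papss2, Postn and Slco2a1 among those that fell. The share of calls higher in KO was 47.8%.

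Tekt3 showed the fewest changes, and among genes of at least 5 CPM its largest falls were in globin genes. The globin gene Hbb-bt fell 2.89-fold (32 ± 10.8 against 92.6 ± 2.36 CPM, n = 3 each), Hba-a1 1.44-fold (448 ± 39 against 644 ± 10.9) and the haem synthesis enzyme Alas2 1.53-fold (47.6 ± 4.57 against 73 ± 0.909, adjusted p = 2.06e-06). Cdh1 rose 2.17-fold (30.9 ± 4.14 against 14.2 ± 1 CPM) and Gli1 1.68-fold (77 ± 7.09 against 45.7 ± 4.31), from the highest WT levels of both genes among the strains. Nppa fell 1.3-fold (858 ± 37 against 1120 ± 9.44 CPM).

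In the libraries labelled Tekt3 KO, 631 genes rose and 942 fell of 15328 tested (10.3%), 25 and 44 of them by at least 1 log2 unit. Erythroid genes fell in 21 of 26 cases and rose in 0 (26 fell adjusted over the list alone; adjusted p = 0.146 with an estimated correlation), including Hbb-bs (2.22-fold). The blood group genes Rhd and Kel fell 2.09-fold and 2.04-fold. Haemoglobin genes made up 0.429 ± 0.0433% of counts in KO and 0.61 ± 0.00964% in WT (exact p = 0.1, n = 3 each). Macrophage and platelet genes fell in 4 of 19 cases and rose in 0 (6 fell adjusted over the list alone; adjusted p = 0.295 with an estimated correlation), with Itga2b falling 1.67-fold and Pf4 1.64-fold. Endoderm genes rose in 15 of 22 cases and fell in 0 (18 rose adjusted over the list alone; adjusted p = 0.146 with an estimated correlation), from a mean log2 CPM of 2.25 in WT, the highest of the WT groups, to 2.93. Hedgehog genes rose in 10 of 23 cases and fell in 1 (15 and 4 adjusted over the list alone; adjusted p = 0.295 with an estimated correlation), with Ptch1 at 1.33-fold and Shh at 1.77-fold. Outflow tract genes rose in 8 of 24 cases and fell in 3 (8 and 5 adjusted over the list alone; adjusted p = 0.196 with an estimated correlation), with the semaphorin receptor Nrp2 at 1.42-fold and Rgs5 at 1.68-fold, and Isl1 rose 1.71-fold.

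Sarcomere and calcium handling genes fell in 17 of 46 cases and rose in 0 (24 fell adjusted over the list alone; adjusted p = 0.373 with an estimated correlation), with Slc8a1 falling 1.34-fold. Endothelial and endocardial genes fell in 12 of 37 cases and rose in 2 (13 and 3 adjusted over the list alone; adjusted p = 0.295 with an estimated correlation), with the flow-responsive factor Klf2 falling 1.69-fold and Tek 1.25-fold. Epicardial genes fell in 8 of 22 cases and rose in 0 (11 and 1 adjusted over the list alone; adjusted p = 0.295 with an estimated correlation), with Tbx18 falling 1.32-fold. Further rises were Vwa2 (2.54-fold), Arg1 (2.26-fold), Eps8l2 (2.18-fold), Magel2 (2.16-fold), Cldn4 (2.15-fold), Nkx2-6 (2-fold) and Lin28a (1.98-fold), and further falls Nfix (2.04-fold), Wdfy2 (1.93-fold), Plek (1.9-fold), Lgals9 (1.89-fold), Postn (1.46-fold) and Tbx20 (1.26-fold).

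The Tekt3 count fell to 113 in a fit of all 38 libraries, 115 on log2(TPM + 1) and 87 with the WT libraries summed to 1, and to 728, 764 and 724 without WT library 1, 2 or 3. With summed WT libraries 9 erythroid, 1 sarcomere, 2 endothelial, 0 epicardial and 1 macrophage and platelet gene fell, and 4 endoderm, 3 hedgehog and 2 outflow tract genes rose. On log2(TPM + 1), 10 erythroid, 4 sarcomere, 3 endothelial and 0 epicardial genes were lower, and 4 endoderm, 3 hedgehog and 3 outflow tract genes higher. Of calls, 40.1% were higher in KO. Of 34 named genes 26 were no longer called in the fit of all libraries and 8 with summed WT libraries.

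In Mlf1, the hedgehog targets Gli1 and Foxf1 rose and Nppa and Myl2 fell, although the targeted gene was not called lower. In the libraries labelled KO, Gli1 and Foxf1 rose 10-fold (89.6 ± 11.2 against 8.94 ± 1.37 CPM) and 8.91-fold (87.8 ± 4.68 against 9.86 ± 0.849, adjusted p = 1.38e-13, n = 3 each). Nkx6-1, expressed in foregut and neural progenitors, rose 29.4-fold (24.4 ± 6.03 against 0.824 ± 0.071 CPM) and Nkx2-1 21.5-fold (20.1 ± 3.55 against 0.927 ± 0.225). Nppa fell 2.6-fold (947 ± 77.6 against 2460 ± 30.2 CPM), and the ventricular myosin light chain Myl2 2.07-fold (1340 ± 43.2 against 2790 ± 96.6). The mitochondrial cytochrome oxidase gene mt-Co1 fell 2.46-fold (2270 ± 436 against 5580 ± 244 CPM).

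Of 14422 genes tested, 4002 rose and 3789 fell (54%), 1176 and 282 of them by at least 1 log2 unit. All 22 tested endoderm genes rose (22 adjusted over the list alone; adjusted p = 0.022 with an estimated correlation), with Cdh1 at 7.99-fold, Cldn6 at 6.61-fold and Esrp1 at 10.6-fold, and a list mean log2 CPM of 1.57 in WT and 3.64 in KO. Of 16 lung and splanchnic mesenchyme genes 15 rose and 0 fell (15 rose adjusted over the list alone; adjusted p = 0.0601 with an estimated correlation), and Fendrr and Tbx4 rose 25-fold and 12.7-fold. Of 24 hedgehog genes 20 rose and 2 fell (20 and 2 adjusted over the list alone; adjusted p = 0.0392 with an estimated correlation). Second heart field genes rose in 16 of 22 cases and fell in 2 (16 and 2 adjusted over the list alone; adjusted p = 0.022 with an estimated correlation), with Isl1 at 3.74-fold. Neural crest genes rose in 20 of 25 cases and fell in 3 (20 and 3 adjusted over the list alone; adjusted p = 0.0392 with an estimated correlation), with Sox10 at 5.87-fold and Alx4 at 14.6-fold. FGF and retinoic acid genes rose in 22 of 30 cases and fell in 1 (22 and 1 adjusted over the list alone; adjusted p = 0.0311 with an estimated correlation), with Stra6 at 7.8-fold. Primary cilium genes rose in 35 of 69 cases and fell in 5 (35 and 5 adjusted over the list alone; adjusted p = 0.272 with an estimated correlation), with Tmem231 at 1.88-fold. Wnt7b (17.1-fold), Msc (13-fold), Mfap4 (3.67-fold), Notch3 (2.82-fold), Nr2f2 (2.72-fold) and Kmt2d (2.27-fold) also rose.

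Sarcomere and calcium handling genes fell in 42 of 46 cases and rose in 1 (42 and 1 adjusted over the list alone; adjusted p = 0.0849 with an estimated correlation), with Tnni3 falling 2.14-fold. All 44 oxidative phosphorylation genes fell (44 adjusted over the list alone; adjusted p = 0.118 with an estimated correlation), with Sdhb falling 1.94-fold. Ribosomal protein genes fell in 64 of 78 cases and rose in 0 (69 fell adjusted over the list alone; adjusted p = 0.503 with an estimated correlation), with Rps14 falling 1.72-fold, and on TPM 19 were higher and 16 lower. Endothelial and endocardial genes fell in 20 of 37 cases and rose in 6 (21 and 6 adjusted over the list alone; adjusted p = 0.503 with an estimated correlation), with Ramp2 falling 1.92-fold, and on TPM 12 were higher and 11 lower. Macrophage and platelet genes fell in 8 of 17 cases and rose in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.414 with an estimated correlation), with the lysozyme gene Lyz2 falling 2.29-fold. The natriuretic peptide gene Nppb fell 2.81-fold, Ctsk 3.01-fold, Postn 2.98-fold, Tm4sf1 2.92-fold, Tnfrsf12a 2.89-fold, Igfbp7 2.81-fold, Mb 2.76-fold, Klf2 2.74-fold and Bmp10 1.69-fold.

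With the WT libraries of Mlf1 summed to 1, 4861 genes were called, 20 endoderm and 17 primary cilium genes rose, and 39 ribosomal protein genes fell. On TPM 54 primary cilium genes were higher. Genes higher in KO were 51.4% of calls, and 88.2% on TPM, where the median of all genes was higher by 0.368.

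**Figure D3:**
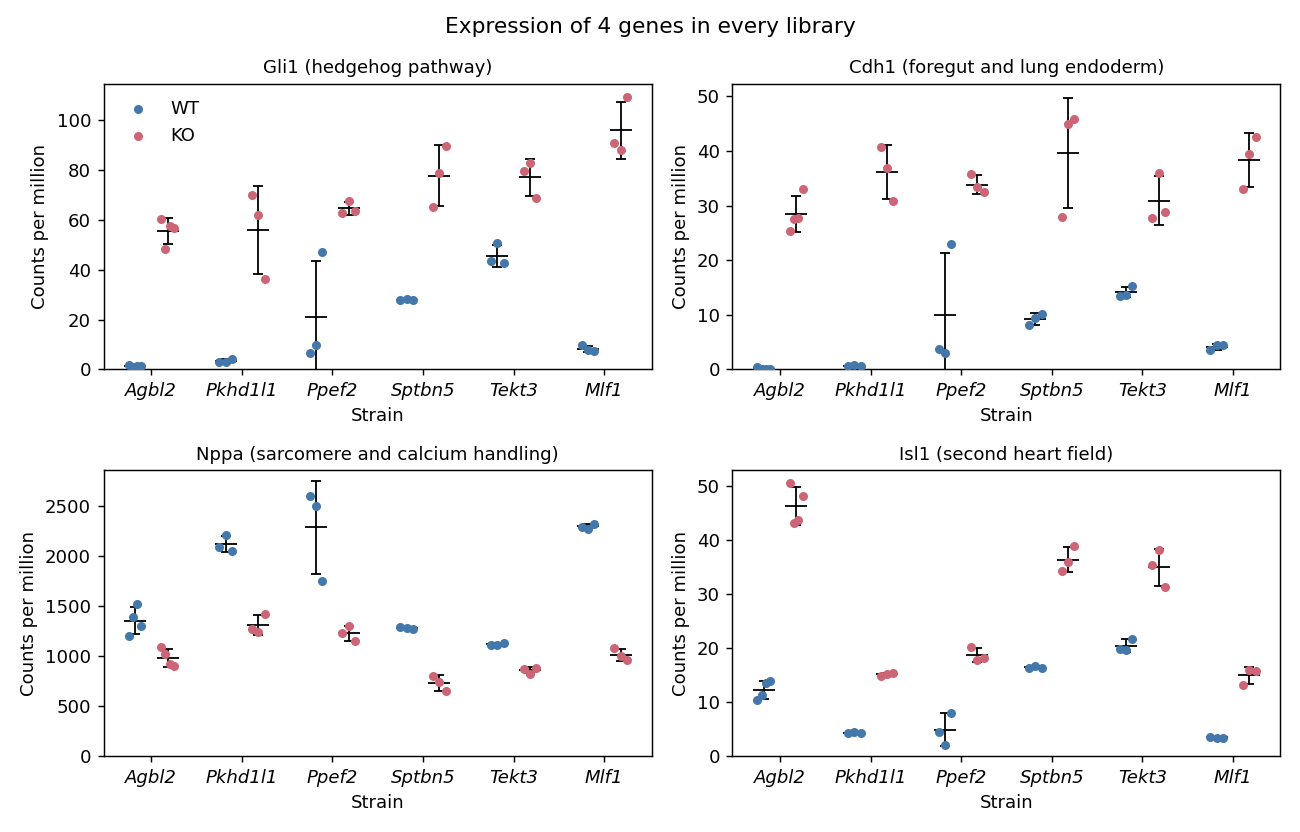
CPM of Gli1, Cdh1, Nppa and Isl1 in every library, by strain, with points for libraries and bars for means ± SD. Mean Gli1 lies between 55.6 and 95.9 in the KO groups and between 1.45 and 45.6 in the WT groups, and WT library 3 of Ppef2 is at 46.9.

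Over the 6 strains together, with strain as a covariate, 5159 genes rose and 4547 fell of 16437 tested. Libraries, not strains, were the replicates in this fit, and some WT libraries may be repeats of 1 sample. Its adjusted p therefore does not measure the spread of the effect between strains and may be too small. The LIM homeodomain gene Isl1, a marker of second heart field precursors, rose 2.8-fold (log2 fold change 1.48, SE 0.0961, adjusted p = 2.14e-14, 19 KO and 19 WT libraries). Tek, an endothelial receptor tyrosine kinase, fell 1.47-fold (−0.56, SE 0.0348, adjusted p = 4.46e-15), Nfatc1 1.5-fold and the conduction connexin Gja5 1.5-fold. Further rises by smallest p were the surface antigen Cd24a (1.73-fold), the stem cell factor Sall4 (1.82-fold), Ptma (1.53-fold), the chromatin genes Cbx1 (1.45-fold), Hmgb3 (1.39-fold) and Sinhcaf (1.59-fold), Fndc3c1 (2.27-fold), the junction gene Cgn (2.34-fold) and Fignl2 (1.62-fold). Further falls were Fads3 (1.58-fold), Aldh1b1 (1.62-fold), the potassium channels Kcnk3 (1.79-fold) and Kcnj11 (1.57-fold), Gsn (1.62-fold), Gsg1l (1.71-fold) and Sardh (1.9-fold).

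All 23 tested endoderm genes rose in the common comparison (adjusted p = 0.263 with an estimated correlation). Lung and splanchnic mesenchyme genes rose in 14 of 16 cases and fell in 0 (adjusted p = 0.308 with an estimated correlation), second heart field genes in 17 of 22 with 2 lower (adjusted p = 0.242), neural crest genes in 20 of 26 with 3 lower (adjusted p = 0.31) and hedgehog genes in 18 of 24 with 3 lower (adjusted p = 0.31). FGF and retinoic acid genes rose in 22 of 31 cases and fell in 2 (adjusted p = 0.198 with an estimated correlation), Wnt genes in 23 of 41 with 8 lower (adjusted p = 0.395) and primary cilium genes in 41 of 70 with 6 lower (adjusted p = 0.143). Neural tissue genes rose in 15 of 21 cases and fell in 2 (adjusted p = 0.394 with an estimated correlation), pharyngeal and skeletal muscle precursor genes in 9 of 13 with 1 lower (adjusted p = 0.395), liver genes in 15 of 19 with 1 lower (adjusted p = 0.568) and outflow tract genes in 13 of 24 with 7 lower (adjusted p = 0.395).

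Sarcomere and calcium handling genes fell in 46 of 48 cases and rose in 0 (adjusted p = 0.119 with an estimated correlation), and all 44 oxidative phosphorylation genes fell (adjusted p = 0.31). Mitochondrially encoded genes fell in 11 of 13 cases and rose in 0 (adjusted p = 0.316 with an estimated correlation), endothelial and endocardial genes in 26 of 37 with 6 higher (adjusted p = 0.119; the median turned positive on TPM in Mlf1) and extracellular matrix genes in 20 of 36 with 9 higher (adjusted p = 0.484; positive on TPM in Ppef2). Erythroid genes fell in 22 of 26 cases and rose in 0 (adjusted p = 0.412 with an estimated correlation; the median turned positive on TPM in Ppef2), and macrophage and platelet genes in 10 of 21 with 0 higher (adjusted p = 0.31). Hypoxia and glycolysis genes fell in 16 of 34 cases and rose in 6 (adjusted p = 0.568 with an estimated correlation), immediate early and heat shock genes in 11 of 25 with 3 higher (adjusted p = 0.395), the medians of both turning positive on TPM in Ppef2 and Mlf1. Ribosomal protein genes fell in 16 of 78 cases and rose in 1 (adjusted p = 0.776 with an estimated correlation), with medians positive on TPM in Pkhd1l1, Ppef2 and Mlf1.

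The other lists were not called by camera in the common comparison at the preset correlation. Cardiac transcription factors rose in 9 of 32 cases and fell in 16 (camera adjusted p = 0.11), cushion mesenchyme genes in 6 and 12 of 30 (0.0781), epicardial genes in 5 and 10 of 22 (0.0777) and tubulins and their modifying enzymes in 5 and 15 of 30 (0.306). Cell cycle genes rose in 18 of 42 cases and fell in 4 (camera adjusted p = 0.243), motile cilium genes in 14 and 6 of 36 (0.163), p53 and apoptosis genes in 4 and 6 of 25 (0.428) and the human tetralogy of Fallot genes in 11 and 12 of 29 (0.843). For 3 lists the median and the camera direction differed in sign: BMP and TGF-beta genes (13 higher and 13 lower of 39, median 0.031, camera down, adjusted p = 0.243), Notch genes (10 and 7 of 21, median −0.013, camera up, adjusted p = 0.682) and histones (2 and 1 of 28, median 0.064, camera down, adjusted p = 0.962). The liver list had a camera adjusted p of 0.0503 and so was not called either. Adjusted over the list alone, the common counts differed by at most 1 gene per direction except for ribosomal proteins (0 higher and 0 lower), histones (0 higher), primary cilium genes (43 higher), tubulins (7 higher) and pharyngeal and skeletal muscle precursors (12 higher).

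Of 13763 genes tested in all 6 strains, 120 were called higher in every strain and 225 lower, where shuffling the calls within strains gave means of 0.24 and 0.555. Hoxb1, Ptch1, Rab23, Isl1, Fendrr, Rbpj, Nrp2 and Rgs5 were higher in all 6, and Gja5, Gata4, Nppa, Eng, Nos3, Tgfb1, Postn, Bmp10, Tek and Nfatc1 lower in all 6. The common count was 7625 with the WT libraries of each strain summed to 1, 9809 without WT library 3 of Ppef2 and 1995 with the endoderm score as a covariate, all chosen after the data were seen. With that score in the fit, hedgehog genes rose in 1 case and fell in 3 (median log2 fold change 0.04, against 0.64 without it), and neural crest genes in 0 and 1 (−0.02 against 1.54). Sarcomere genes then fell in 15 cases (−0.32 against −0.56), endothelial and endocardial genes in 17 (−0.26 against −0.25) and macrophage and platelet genes in 7 (−0.48 against −0.30).

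**Figure D4:**
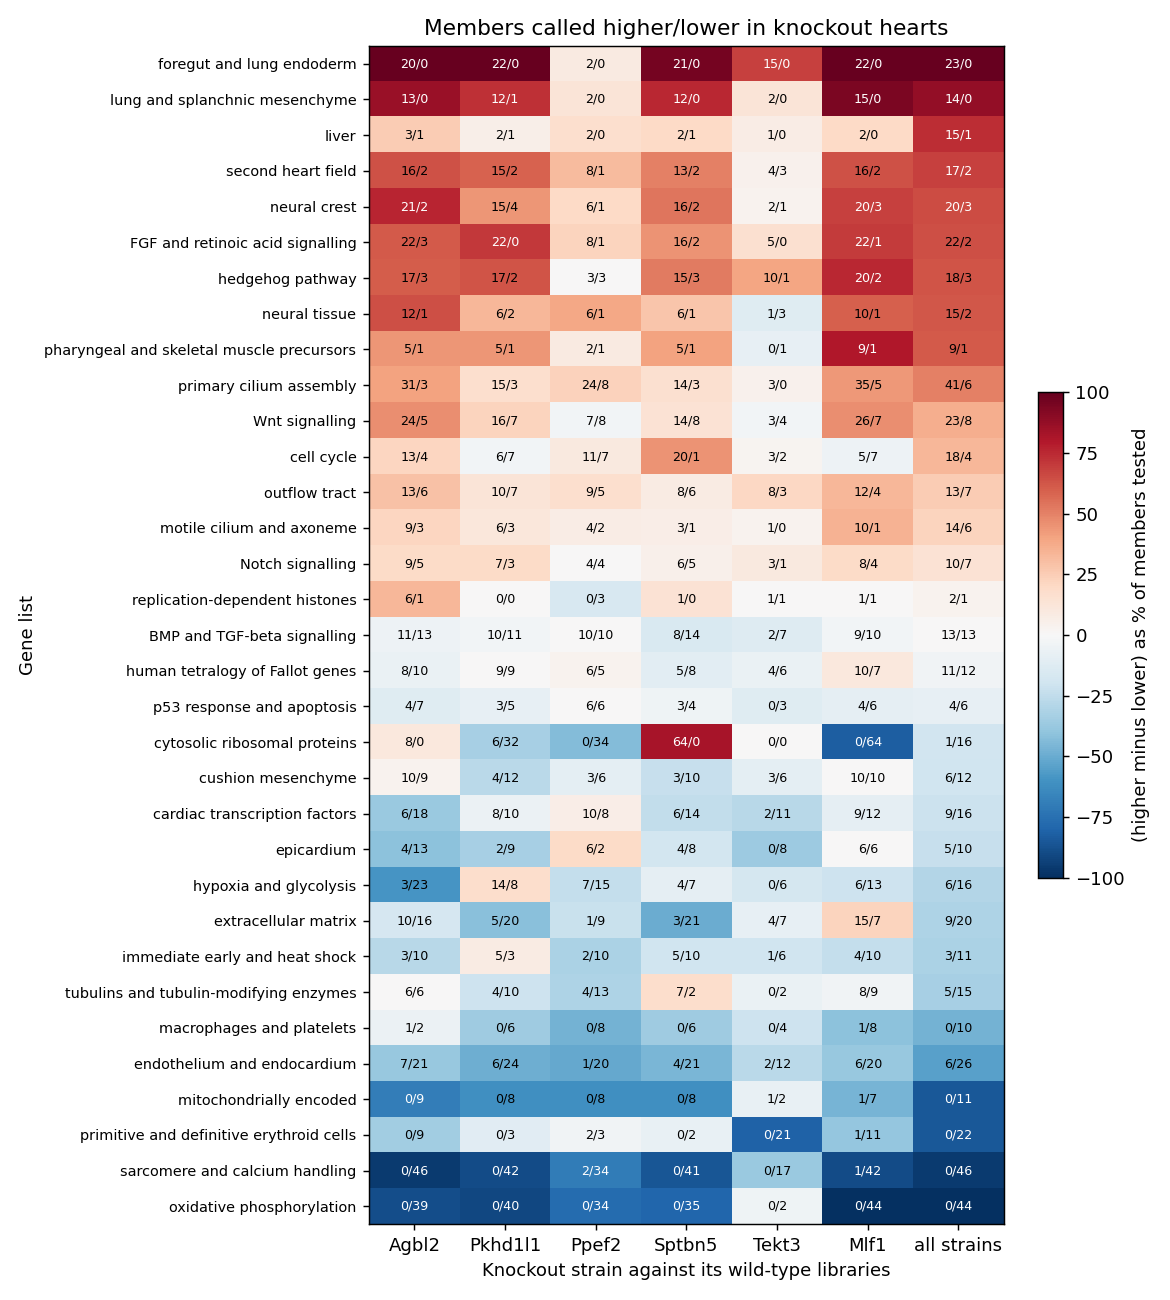
Numbers of list members called higher and lower in KO (higher/lower) for 33 gene lists in each strain and in all strains together. Colour is higher minus lower as a percentage of the members tested. In all strains together 23 of 23 endoderm genes rose and 44 of 44 oxidative phosphorylation genes fell; the ribosomal protein and some smaller counts change direction on TPM in Pkhd1l1, Ppef2 and Mlf1.

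All 15 pairs of strains shared more calls in each direction than independent lists would. Agbl2 and Pkhd1l1 shared 1649 higher genes against 597.9 for independent lists and 1708 lower genes against 709.7, while 159 genes were called in opposite directions against 1303. Across genes, which are not independent replicates, the Pearson correlation of their log2 fold changes was 0.825, the highest of 15 pairs. The lowest was 0.206, for Ppef2 and Tekt3, which shared 219 higher genes against 140.8 and 331 lower genes against 209.1. Each strain had its own WT libraries, so no pair shared controls.

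The effect differed between strains in 9604 of 16437 genes. Shh rose in 5 strains, from 1.77-fold in Tekt3 to at least 633-fold in Agbl2, and its change differed between them (adjusted p = 8.28e-06 for the difference, edgeR). For the same gene in Ppef2, the log2 fold change was 1.69 (SE 0.752, adjusted p = 0.11). The KO groups had similar mean log2 CPM over the endoderm list, within a range of 0.71, while the WT groups ranged over 3.22.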

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

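The counts over other splits of the libraries and the tests of the difference between strains were chosen before the data were examined, and the tests of neighbouring tissue, cardiomyocyte share, loss of the targeted gene, 1 RNA pool, repeated deposits, a swap and a wrong label only after the results were seen.

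Single libraries were tested only in Agbl2, with 4 libraries per group. There 7 of 78 values stood apart from the other libraries of their group (gap to range above Dixon's 0.829), where chance gives about 1 in 20. KO library 1 had a mitochondrial share of 3.61%, against 2.84 to 2.89% in the other KO libraries. Among KO libraries, 1 stood highest in mean log2 CPM of cushion mesenchyme genes (5.89 against 5.73 to 5.75), 1 highest in epicardial genes (4.38 against 4.29 to 4.3) and 1 lowest in immediate early and heat shock genes (4.04 against 4.12 to 4.13). Among WT libraries, 1 stood highest in neural crest genes (1.7 against 1.42 to 1.44), 1 lowest in the tetralogy of Fallot genes (5.35 against 5.49 to 5.5) and 1 highest in extracellular matrix genes (7.03 against 6.86 to 6.88).

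The KO effect differed between strains in 9604 genes. For a list called in opposite directions, the highest median among strains called up was set against the lowest among strains called down. These pairs were picked on the same data, so the p-values of their differences are too small. Extracellular matrix genes had a median log2 fold change of 0.15 in Mlf1 (15 rose and 7 fell of 36) and −0.34 in Sptbn5 (3 and 21), and limma's camera gave p = 3.28e-06 for the difference and p = 0.168 with an estimated correlation. Cytosolic ribosomal protein genes had a median of 0.17 in Sptbn5 (64 rose and 0 fell of 78) and −0.49 in Ppef2 (0 and 34, but 21 higher and 5 lower on TPM), with p = 7.13e-26 for the difference and p = 0.101 with an estimated correlation.

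In Agbl2, 1 of 35 splits, the real one, gave as many genes (6646, highest other 0). The same held for the common effect (1 of 31 splits, 9706 genes, highest other 0). For the difference between strains it was also 1 of 31 splits (9604 genes, highest other 3360). These shares are under 0.05 but are the smallest that the splits can give. The splits over all strains treat libraries as separate samples, which the WT triplicates of Pkhd1l1, Sptbn5, Tekt3 and Mlf1 may not be. Shuffling genotype within strains also removes the common effect, so it does not test the difference between strains alone. For the other strains 10 splits are too few for a share under 0.05. The real split and the highest other gave 5765 and 0 genes in Pkhd1l1, 6430 and 0 in Ppef2, 4644 and 0 in Sptbn5, 1573 and 2 in Tekt3, and 7791 and 0 in Mlf1.

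Over the 6 strains together, endoderm, lung mesenchyme and hedgehog genes were higher in KO libraries (adjusted p = 0.263, 0.308 and 0.31 with an estimated correlation). In Ppef2 only 2 of 22, 2 of 16 and 3 of 24 rose, with 3 hedgehog genes lower, and in Tekt3 only 2 of 16 mesenchyme genes rose. Without WT library 3 of Ppef2, 21 of 23, 12 of 16 and 16 of 24 rose in that strain. Then 1 mesenchyme and 3 hedgehog genes fell, and genotype and fragment length coincide in that comparison. A lower share of cardiomyocytes, with every other cell type raised alike, is argued against by the endothelial list, whose common median was −0.25 (26 of 37 fell; adjusted p = 0.119 with an estimated correlation) while that of the endoderm list was 2.20, and on TPM in Mlf1, where the endothelial median turned positive, the medians were 0.106 and 1.81. Differing amounts of foregut and pharyngeal tissue on the dissected hearts may contribute and stay open. Differences between WT groups correlated over genes with the KO change of a strain outside the pair at a median r of 0.215. The range was −0.6 to 0.77 over 60 combinations. Many of these WT pairs join strains from both sets that the first principal component separates. The median therefore also carries that split and cannot gauge tissue alone. Of 23 measured endoderm genes, 4 are in another list and 6 were over 1 CPM in every WT group, the most abundant being Krt8 (35.6 to 103 CPM over WT groups, 50.5 to 130 over KO groups). Loss of the targeted gene stays open and untested, because the ratio of the range of KO minus WT differences to that of WT levels, 1.07, is fixed near 1 by the narrow range of KO levels (0.71 log2 units, against 3.22 between WT groups), and dissection and genotype cannot be told apart in this design.

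WT triplicates of Pkhd1l1, Sptbn5, Tekt3 and Mlf1 varied less than their KO triplicates. A library deposited more than once is argued against, since the smallest chi-square per degree of freedom over genes was 1.97. Repeat libraries of 1 RNA pool are a candidate explanation: the balance of Xist to Y-linked counts, which follows the embryos in a pool, had a median chi-square per degree of freedom of 0.755 in these triplicates (0.153 in Pkhd1l1, 0.439 in Mlf1, 1.07 in Sptbn5 and 4.33 in Tekt3, above counting noise) and 184 in their KO triplicates. In the titles, a number shared by the WT libraries of a strain stands before the replicate number in these strains and in Ppef2, where that chi-square was 89.8 in WT, which argues against the number marking 1 sample there. If the libraries of the 4 triplicates are repeats, adjusted p may be too small in their strains and in the fits of all strains. No biological explanation was tested.

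WT library 3 of Ppef2 lay apart from WT libraries 1 and 2. A swap with a KO library is argued against, because the lowest KO endoderm level exceeded the highest of WT libraries 1 and 2 by 1.78 log2 units, so no KO library was out of place. Whether it is a KO library under a WT label stays open. Over 9085 genes called between KO and WT libraries 1 and 2, WT library 3 lay at a median position of 0.446. The quartiles were 0.142 to 0.751, with 0 at those WT libraries and 1 at KO. KO libraries lay at 0.928 to 1.08, but they helped to choose these genes and set position 1. A KO library left out of that choice would lie lower by an unknown amount. WT libraries 1 and 2 also differ from WT library 3 and KO in fragment length. WT library 3 lay at 0.932 for endoderm, 0.915 for ribosomal protein, 0.889 for neural crest and 0.877 for hedgehog genes. It lay at 0.869 for lung mesenchyme and 0.708 for oxidative phosphorylation genes, but at 0.14 for hypoxia and glycolysis and 0.295 for endothelial genes. A library of other embryos or another preparation may explain this and was not tested, but its fragment length of 354.9 bases lay near the 345.7 to 349.1 of the KO libraries, while WT libraries 1 and 2 were at 266.4 and 264.5.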

How the results depend on the processing

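The sums of WT libraries, the comparison without WT library 3 of Ppef2 in the common effect and the endoderm score as a covariate were chosen only after the results were seen. Values were taken over 236 pairs of a named gene and a comparison, in which a gene can recur, and the settings run for each. Of 3791 values, 3645 kept their side of the threshold and, where called, their direction. Of the rest, 145 were no longer called, 1 became called and 0 that were called reversed. The uncalled Mlf1 change of its own gene, 0.06 in the main fit, was −0.03 without KO library 1 and −0.08 without WT library 1. With the WT libraries summed to 1, genes called numbered 3598 in Agbl2, 1715 in Pkhd1l1, 878 in Sptbn5, 87 in Tekt3 and 4861 in Mlf1, below the counts from separate libraries, and 7555 in Ppef2, above its 6430; the cause was not tested. A threshold of 1 log2 unit left 823, 681, 992, 384, 69 and 1458 genes in Agbl2, Pkhd1l1, Ppef2, Sptbn5, Tekt3 and Mlf1. On log2(TPM + 1) limma called 2829 genes in Sptbn5 and 115 in Tekt3, and a fit of all 38 libraries called 113 in Tekt3, again with no test of the cause. The common effect fell to 1995 genes with the endoderm score, which is itself higher in KO libraries, as a covariate. Of 107 list calls in the strains, 19 held with an estimated correlation.

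The Agbl2 change of its own gene was no longer called on log2(TPM + 1) (−0.26), with the replicate block (−0.69), with summed WT libraries (−0.70) or in the fit of all libraries (−0.68), and ran from −0.85 without WT library 2 to −0.56 without WT library 3. Its 19 to 44 counts per library limit that test. The Mlf1 change of its own gene was called on log2(TPM + 1) only (0.38). Leaving out 1 library gave 3933 genes (no WT library 2) to 9094 (no WT library 3) in Ppef2 and 724 (no WT library 3) to 1849 (no KO library 2) in Tekt3. Whether the replicate numbers pair the samples is unresolved with so few libraries. Deviations of same-numbered libraries correlated at −0.32 to 0.16 in Agbl2 and −0.14 to 0.31 in Ppef2. A KO library correlated best with the WT library of its own number in 2 of 3 cases in Ppef2, Sptbn5 and Tekt3. That was so in 1 of 4 cases in Agbl2 and 1 of 3 in Pkhd1l1 and Mlf1. With the number as a block, edgeR called 6086 genes in Agbl2, 5232 in Pkhd1l1, 6006 in Ppef2, 4687 in Sptbn5, 1474 in Tekt3, 7971 in Mlf1 and 8875 in common.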

Other observations

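The test of genes near the targeted gene was written before its result was seen, and the genes in the next paragraph were chosen after their values were seen.

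Hedgehog ligands moved in opposite directions. Dhh, which endothelial cells make, fell in each of the 6 strains, by 0.45 log2 units in Agbl2 and by 1.04 in Mlf1. Its common log2 fold change was −0.75 (edgeR adjusted p = 9.12e-11), while Shh had a common change of 2.97 (adjusted p = 3.39e-07). Pkhd1l1, the gene targeted in 1 strain, was also lower in Agbl2 (−0.80), Sptbn5 (−1.08), Tekt3 (−0.76) and Mlf1 (−0.73) but had a log2 fold change of 0.06 in Ppef2 (adjusted p = 0.772). Malat1, a nuclear noncoding RNA, rose in Pkhd1l1 (0.94), Ppef2 (1.98) and Mlf1 (2.12) and fell in Agbl2 (−0.55), Sptbn5 (−0.73) and Tekt3 (−0.21). EdgeR's adjusted p for the difference between strains was 1.37e-12. The strains where it rose and where it fell are the sets that the first principal component and the mitochondrial share separate. The gene knocked out and that split between strains cannot be told apart here.

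Sequence of another mouse strain around an edited locus could change nearby genes, so genes within 5 Mb of each targeted gene were expected to change by at least 1 log2 unit more often than others. The smallest adjusted p over the 6 strains was 0.157, by two-sided Fisher's exact tests. It came from Ppef2, where 7 of 43 nearby genes changed (16.3% against 6.85% of the others; odds ratio 2.64, from 0.99 to 6.05, exact p = 0.0261). Of the 7, Pf4 and Ppbp are in the macrophage and platelet list, in which 8 of 17 genes fell and 0 rose in Ppef2. The hypothesis stays open, because the bound set beforehand was on p alone and the intervals reach odds ratios of up to 12.7.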
